A study of Mus musculus with 8 samples.

How the data were processed

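RNA was profiled from the whole uterus, with the conceptuses inside it, of 8-week-old pregnant Foxp3DTR female mice collected at embryonic day 8 (E8). These mice carry a diphtheria toxin receptor at the Foxp3 locus, so that the toxin kills cells that express Foxp3, the transcription factor of regulatory T cells. The females had been mated with BALB/c males, an allogeneic cross. Per the labels' protocols, they received 1 µg of diphtheria toxin (DT) or PBS by intraperitoneal injection at E1, E3, E5 and E7, a regimen described as removing 85% of regulatory T cells. The protocol also describes the injections as daily, and the listed days were used here. The labels give 4 DT libraries (replicates 1, 3, 4 and 5) and 4 PBS libraries (replicates 1, 2, 4 and 6), and each library was taken to be 1 female. Because Foxp3 itself did not separate the groups, libraries are called DT-labelled and PBS-labelled.

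Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with Trizol and had integrity numbers of 8 to 10, and libraries made with the Kapa mRNA hyperprep kit were sequenced on a NextSeq 500 as paired reads of about 75 bases. The protocol also names the Illumina TotalPrep RNA Amplification Kit. The authors deposited whole-number read counts per Ensembl gene, with no normalization, in 1 table per library and in 1 table of the whole series. Per the submitters' processing notes, Trimmomatic, HISAT2, featureCounts, SAMtools and DESeq2 were used with genome build GRCm38. Their versions and roles, the annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Reads from overlapping genes on opposite strands, and from near-identical gene copies, therefore could not be told apart.

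Each count table held 49585 genes. The series table and the per-library tables differed in 0 cells. By Ensembl ID, 49326 genes matched the GENCODE mouse M21 annotation of GRCm38, which gave symbols and coordinates. The other 259 IDs held 0.076% of the counts and were kept in the tests under their IDs. Total counts ranged from 94794512 to 109847604 per library. At this depth differences between females, not counting error, limited the precision for genes above 1 CPM. Over the 28 pairs of libraries the smallest chi-square per degree of freedom was 28.81, so no pair agreed within sampling noise and each library was counted once.

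Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total count of 15, which left 22693 genes, and libraries were scaled by TMM factors. DT-labelled and PBS-labelled libraries were compared with the robust quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with treatment as the only term. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The common dispersion was 0.0626, a biological coefficient of variation of 25%. Log2 fold changes are DT minus PBS, their standard errors come from the fit, and CPM values (counts scaled to the library total) use the TMM-scaled library sizes and are given as mean ± SD over 4 libraries.

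Before the data were examined, the test, 55 lists of marker and pathway genes, the rule for naming genes and the alternative settings were fixed. Lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 55 lists. Camera was also run with the correlation estimated from the data, which allows for members of a list that vary together between females, and fry was run beside it. List members were counted at adjusted p under 0.05 over all genes and again adjusted over the list alone. Several lists share members, such as C1qa in the macrophage and complement lists and Ciita in the interferon-gamma and MHC class II lists, so their tests are not independent.

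Genes were named by this rule. Foxp3 and Hbegf, whose human homologue encodes the diphtheria toxin receptor, were named in every case. Among genes past the threshold, with a mean log2 CPM of at least 0, with no overlap between groups and without a predicted-model symbol, the 10 with the largest and the 10 with the smallest log2 fold change were taken. Where fewer than 10 passed in a direction, the next by unadjusted p were added and said not to pass. For each list past the threshold, and for 7 lists in every case (regulatory T cells, T cells, uterine NK cells, macrophages, decidual stroma, trophoblast prolactins and type 2 immunity), up to 4 members with the smallest unadjusted p were named, 105 genes in all. For each named gene, the share of 75-base windows of its exons that occur in the exons of another annotated gene was computed in Python 3.11.15, and a share of at least 10% is given beside the gene.

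Shares of counts held by mitochondrially encoded genes, the 10 most abundant genes, Y-linked genes, adult haemoglobins and embryonic globins, and the total count, were compared by two-sided exact permutation tests over the 70 arrangements of 4 and 4 libraries, whose smallest possible p is 0.0286. The share held by genes that take up ribosomal RNA reads (Gm42418, CT010467.1 and Lars2) was added after the data were seen. A conceptus score, the mean z-score of the trophoblast prolactin, trophoblast lineage, yolk sac endoderm and primitive erythroid lists, was also defined after the data were seen. Principal components were taken from log2 CPM (prior count 2) of the 500 most variable genes. Correlations over the 8 libraries have exact permutation p-values, adjusted over the 9 relations computed.

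Alternatives were other scalings (RLE, upper quartile, library size only), other filters on low counts, DESeq2 1.42.0, limma voom with sample weights, 1 surrogate variable (sva 3.50.0), the replicate number as a block, the suffix of the sample titles as a nested term, a test against a 1.2-fold change, abundant genes left out, and each library left out in turn. The fitting procedure was tested on counts simulated from the 8 libraries over 22356 genes with known changes. It recovered 10.4% of genes changed 1.5-fold, 46% of those changed 2-fold, 94% of those changed 4-fold and 95.9% of those changed 8-fold, and 6 of 128 calls (4.69%) were false. In these simulated counts, changes below 2-fold were therefore mostly below what 4 libraries against 4 could detect. In the same simulation, camera called 0 of 40 lists with no change. Genes were simulated independently of each other, so this could not show how camera behaves on lists whose members vary together. For the same reason the recovery and false-call rates may not hold for the real libraries, where many genes vary together.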

Results

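Gene expression in the whole pregnant uterus at E8 was compared between females given diphtheria toxin to deplete regulatory T cells and females given PBS, 4 libraries per group. Regulatory T cells restrain immune responses, including those against paternal antigens carried by the conceptus, and the comparison addressed what their depletion changes in uterine gene expression after implantation. Total counts ranged from 94794512 to 109847604 per library, a spread of 1.16-fold. The totals of the groups differed by less than the replicate spread (two-sided exact permutation p = 0.714, n = 4 each).

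Foxp3, the gene whose locus carries the toxin receptor, was not lower in the DT-labelled libraries. It measured 5.12, 5.1, 5.72 and 5.69 CPM in DT-labelled replicates 1, 3, 4 and 5, and 4.89, 4.36, 5.44 and 4.86 CPM in PBS-labelled replicates 1, 2, 4 and 6. The group means were 5.41 ± 0.345 and 4.89 ± 0.44 CPM (SD, n = 4 each), a log2 fold change of 0.15 ± 0.10 (SE; edgeR quasi-likelihood, adjusted p = 0.595) with a 95% confidence interval of -0.09 to 0.38. Foxp3 (ENSMUSG00000039521) lies on the plus strand of chromosome X at positions 7573644 to 7595245 of GRCm38. Its exons overlap those of Flicr, Ccdc22 and Gm36995, and 18.9% of its 75-base windows occur in another annotated gene, so its count may include reads of these neighbours. Foxp3 therefore gave no check of the labels. The measured ratio of Foxp3 to Cd3e, a subunit of the T cell receptor complex, did separate the groups. It was 4.22, 4.47, 4.28 and 3.53 in the DT-labelled libraries and 23.6, 26.4, 13.7 and 16.6 in the PBS-labelled libraries. Cd3e was higher in the DT-labelled libraries, and Foxp3 did not pass the test. Among the other regulatory T cell genes, Il2ra, the alpha chain of the interleukin-2 receptor, had a log2 fold change of -1.71 ± 0.64 (SE; edgeR adjusted p = 0.553), and Tnfrsf9 one of -0.75 ± 0.45. Ikzf2 had a log2 fold change of 0.40 ± 0.22 and the inhibitory receptor Tigit one of 0.65 ± 0.12 (edgeR adjusted p = 0.107), and none of these passed the test. The negative values of Il2ra and Tnfrsf9 rested on PBS-labelled replicates 1 and 2. Il2ra measured 10.2 and 18.6 CPM there, 1.96 and 4.54 in PBS-labelled replicates 4 and 6, and 1.67 to 3.73 in the DT-labelled libraries. Tnfrsf9 measured 98.1 and 128, 34.9 and 48.8, and 23.6 to 64.6 CPM in the same order. Of the 14 measured members of the regulatory T cell list, 0 passed over all genes by edgeR, against 1 higher by DESeq2, 1 higher by limma voom and 1 higher and 1 lower at an unadjusted p under 0.05. By edgeR, 1 member, Tigit, rose when adjusted over the list alone (median log2 fold change 0.17, camera adjusted p = 0.285, fry adjusted p = 0.0318). Hbegf, the mouse homologue of the toxin receptor gene, had a log2 fold change of -0.31 ± 0.17 (edgeR adjusted p = 0.571).

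Genes of the interferon response, antigen presentation and T cells were higher in the DT-labelled uteri. Of 22693 genes tested, 73 rose and 1 fell (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and the 4 DT-labelled libraries did not overlap the 4 PBS-labelled libraries for any of these 74 genes. Over all genes tested, 755 lay above and 393 below without overlap, against 2.86% of genes in both directions together by chance. The median log2 fold change of the 73 genes was 1.28. DESeq2 called 270 genes higher and 71 lower, and limma voom 204 higher and 17 lower. Among called genes with a mean log2 CPM of at least 0 and without a predicted-model symbol, the 10 with the largest fold were all interferon-inducible GTPases or class I antigen-presentation genes: Tgtp1, Tgtp2, Igtp, Gbp6, Iigp1, Gbp4, Ifi47, Irgm2, H2-Q7 and Irgm1. Tgtp1 (ENSMUSG00000078922, chromosome 11, 48985327 to 48994172, minus strand) rose from 1.17 ± 0.284 to 12.4 ± 3.8 CPM (SD, n = 4 each), 10.6-fold. Iigp1 (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, plus strand), a GTPase that acts against intracellular pathogens, rose 5.17-fold, from 39.7 ± 4.15 to 205 ± 75.5 CPM. Tgtp1 and Tgtp2 shared 77.2% and 81.4% of their windows with another gene and Gbp6 shared 67.3%, so reads of these 3 genes could not be placed with certainty, whereas Iigp1 and Irgm1 shared 0%.

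The single gene that fell was Jhy (ENSMUSG00000032023, chromosome 9, 40894849 to 40964118, minus strand), a gene linked to hydrocephalus in mice. It measured 1.54 ± 0.346 CPM in the DT-labelled and 4.34 ± 0.447 CPM in the PBS-labelled libraries (SD, n = 4 each), a log2 fold change of -1.50 ± 0.18 (SE; edgeR adjusted p = 0.0314). The next genes on the lower side did not pass. They included Tgfbr3, the betaglycan co-receptor of TGF-beta, with a log2 fold change of -0.44 ± 0.08 (edgeR adjusted p = 0.0796), and Smoc1, a matricellular protein, with -0.45 ± 0.08 (edgeR adjusted p = 0.0826). Minar1, Trpc4, Nrarp, Ccdc141, Rrp12, Fam20c and Atp6v0a1 followed, with log2 fold changes from -0.71 for Minar1 to -0.23 for Atp6v0a1 and edgeR adjusted p from 0.11 to 0.214. Nrarp shared 76.1% of its windows with another gene, so its reads could not be placed with certainty.

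The number of genes called depended on which libraries were included, while the estimates for the called genes moved little. Without DT-labelled replicate 3, 4 or 5, or PBS-labelled replicate 1, 2 or 6, edgeR called 0 genes in either direction, with the smallest adjusted p between 0.0629 and 0.0849. In the same order, 1662, 1091, 1973, 1117, 1066 and 2047 genes had an unadjusted p under 0.05 in these fits. DESeq2 called 195, 191, 197, 185, 211 and 224 genes higher there, and limma voom 229, 191, 122, 107, 107 and 981. Without DT-labelled replicate 1, edgeR called 115 higher and 1 lower, and without PBS-labelled replicate 4, 43 higher and 5 lower. In each of these 8 fits all 73 genes kept a positive log2 fold change and an unadjusted p under 0.05, with a median between 1.17 and 1.32. The 73 genes were chosen from the same 8 libraries and had no overlap between groups. Their kept direction was therefore given in advance and is not separate support. The loss of calls without any of the 6 libraries named holds for every gene described as risen or fallen here. Scaling by library size only shifted the median log2 fold change of all genes to 0.12, against 0.01 with TMM.

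**Figure D1:**
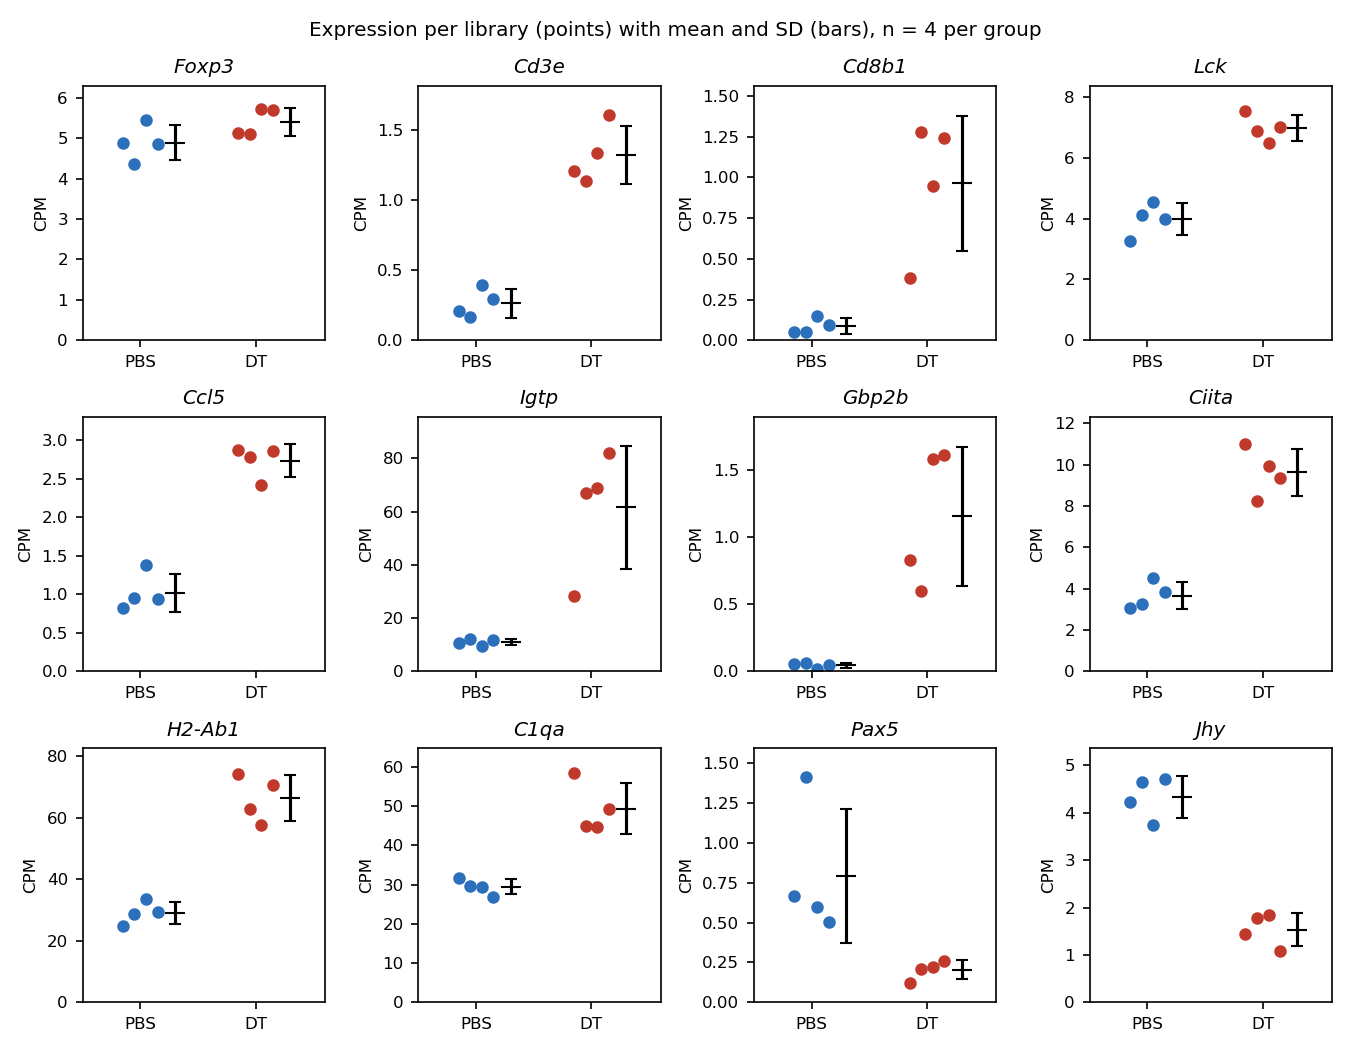
Normalised expression (CPM, linear axes starting at 0) of 12 genes in each of the 4 DT-labelled and 4 PBS-labelled libraries, with points for libraries and bars for mean ± SD. Foxp3 overlapped between groups, whereas Cd3e averaged 1.33 CPM in the DT-labelled and 0.265 CPM in the PBS-labelled libraries and Jhy 1.54 against 4.34 CPM.

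Interferon-gamma response genes had the largest positive median of the 55 lists. Of 20 measured members, 9 rose over all genes and 18 adjusted over the list alone, and 0 fell. The median log2 fold change was 1.55 (camera adjusted p = 1.62e-33, adjusted p = 0.0572 with an estimated correlation, fry adjusted p = 0.0142). Gbp2b, a guanylate-binding protein of cell-autonomous immunity, rose 24.9-fold, from 0.0456 ± 0.0188 to 1.16 ± 0.517 CPM (SD, n = 4 each; edgeR adjusted p = 0.0153). Igtp, an immunity-related GTPase, rose 5.52-fold, from 11.2 ± 1.15 to 61.7 ± 23.1 CPM, and Irgm1 rose 3.13-fold. Interferon-gamma itself, Ifng, with 16.2% of its windows shared with another gene, measured 0.213 ± 0.0593 CPM in the DT-labelled and 0.07 ± 0.00709 CPM in the PBS-labelled libraries, with a log2 fold change of 1.59 ± 0.27 (SE) that did not pass (edgeR adjusted p = 0.0746). Type I interferon-stimulated genes moved less with all 8 libraries. Of 27 measured members, 0 rose by edgeR over all genes, against 14 at an unadjusted p under 0.05, 3 by DESeq2 and 6 by limma voom. Adjusted over the list alone 8 rose, with a median log2 fold change of 0.50. This median was 0.801 without PBS-labelled replicates 1 and 2, and 0.991 without these and DT-labelled replicate 1. The interferon-gamma medians were 1.7 and 1.92 in these fits, which were chosen after the data were seen. Camera called the list (adjusted p = 1.99e-12), but not with an estimated correlation (adjusted p = 0.52). Irf7, a transcription factor of this response, had a log2 fold change of 0.63 ± 0.12 and the antiviral gene Oas2 one of 0.85 ± 0.17, and by edgeR both passed only when adjusted over the list alone, while DESeq2 and limma voom called both over all genes. DT-labelled replicate 1 had the lowest conceptus score of its group (-0.798) and also the lowest interferon-gamma list score (-0.0429, against 0.89 to 1.13 in replicates 3, 4 and 5), still above the 4 PBS-labelled libraries (-1.01 to -0.419). Its type I list score of -0.817 lay within the PBS-labelled range (-1.41 to 0.215), whereas DT-labelled replicates 3, 4 and 5 lay above it (0.571 to 1.23). The size of the type I shift therefore depended on this replicate.

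MHC class II genes, which present antigen to CD4 T cells, also rose. Of 13 measured members, 8 rose over all genes and 9 adjusted over the list alone, with 0 falling and a median log2 fold change of 1.03 (camera adjusted p = 2.01e-28, adjusted p = 0.0572 with an estimated correlation). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a class II beta chain, rose 2.28-fold, from 29.1 ± 3.6 to 66.2 ± 7.5 CPM (SD, n = 4 each; edgeR adjusted p = 0.0153). Ciita (ENSMUSG00000022504), the transactivator of class II genes, rose 2.63-fold, from 3.66 ± 0.64 to 9.63 ± 1.14 CPM (edgeR adjusted p = 0.0175). Ctss, a protease that cleaves the class II invariant chain, rose 1.98-fold, and the peptide-loading gene H2-DMa rose 2.12-fold. In the MHC class I list, 4 of 15 measured members rose over all genes and 14 adjusted over the list alone, with a median log2 fold change of 0.95 (camera adjusted p = 1.43e-20, adjusted p = 0.201 with an estimated correlation). Nlrc5, the transactivator of class I genes, rose 3-fold, from 19.2 ± 2.99 to 57.7 ± 16.2 CPM (edgeR adjusted p = 0.0399). The class I genes H2-Q4, H2-Q6 and H2-Q7 rose 2.44-, 2.99- and 3.14-fold, with 20.7%, 21.1% and 17% of their windows shared with another gene. The MHC class I list score of DT-labelled replicate 1 (-0.3) lay below that of PBS-labelled replicate 2 (-0.224). In DT-labelled replicates 3, 4 and 5 it was 0.633 to 1.42, above every PBS-labelled library.

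T cell genes rose from low levels. Of 20 measured members of the T cell list, 4 rose over all genes and 11 adjusted over the list alone, with 0 falling and a median log2 fold change of 0.68. Camera called the list (adjusted p = 1.35e-13) and did so with an estimated correlation (adjusted p = 0.0308). Cd3e (ENSMUSG00000032093, chromosome 9, 44998740 to 45009627, minus strand) rose 4.95-fold, from 0.265 ± 0.102 to 1.33 ± 0.207 CPM (SD, n = 4 each; edgeR adjusted p = 0.0314). Cd5, a co-receptor of T cells, rose 4.14-fold, the T cell transcription factor Bcl11b 3.5-fold, and the kinase Lck 1.75-fold. Not all members moved together, and 7 of the 20 had a negative log2 fold change. In the cytotoxic lymphocyte list, 2 of 13 members rose over all genes. Adjusted over the list alone, 6 rose and 2 fell, with a median log2 fold change of 0.44 (camera adjusted p = 0.00109, adjusted p = 0.266 with an estimated correlation). Cd8b1, the beta chain of CD8, rose 10.7-fold, from 0.0879 ± 0.0465 to 0.963 ± 0.415 CPM (edgeR adjusted p = 0.0417), while Cd8a had a log2 fold change of 2.93 ± 0.53 that did not pass (edgeR adjusted p = 0.0951). The 2 members lower over the list alone were Gzmb and Prf1, which encode granzyme B and perforin and were named after their values were seen. Their log2 fold changes were -0.84 for Gzmb and -1.38 for Prf1, with edgeR adjusted p over all genes of 0.53 and 0.55. Gzmb measured 82.9 ± 20.1 CPM in the DT-labelled and 149 ± 54.4 CPM in the PBS-labelled libraries. Prf1 measured 45.6 ± 14.6 and 119 ± 80.4 CPM in the same order. These levels lay far above those of Cd8b1, and Prf1 is also in the uterine NK cell list. Which cells the reads of Gzmb and Prf1 came from was not tested. Without PBS-labelled replicate 4 the cytotoxic list was not called (camera adjusted p = 0.135). The Th1 list had 0 of 11 members past the test over all genes by edgeR, against 7 at an unadjusted p under 0.05, 5 by DESeq2 and 4 by limma voom. Adjusted over the list alone 7 rose (median log2 fold change 0.50, camera adjusted p = 8.6e-07, adjusted p = 0.0308 with an estimated correlation). Il18r1, a subunit of the interleukin-18 receptor, was nearest the threshold (log2 fold change 1.15 ± 0.18, edgeR adjusted p = 0.0502).

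Chemokine genes rose as a list. Over all genes, 2 of 23 measured members rose by edgeR, 8 by DESeq2 and 5 by limma voom, and 10 rose adjusted over the list alone, with a median log2 fold change of 0.68 (camera adjusted p = 1.35e-13, adjusted p = 0.0375 with an estimated correlation). Ccl5, which attracts T cells, rose 2.67-fold, from 1.02 ± 0.246 to 2.74 ± 0.215 CPM (SD, n = 4 each; edgeR adjusted p = 0.0322). Ccl2, which attracts monocytes, rose 2.61-fold (edgeR adjusted p = 0.0367). Ccl8 had a log2 fold change of 1.81 ± 0.33 and Ccl3 one of 0.95 ± 0.19. By edgeR both passed only when adjusted over the list alone, and DESeq2 but not limma voom called both over all genes.

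Macrophage and complement lists, which share the C1q genes, were higher. C1qa, a chain of the first complement component that macrophages make, rose 1.68-fold, from 29.4 ± 1.94 to 49.4 ± 6.41 CPM (SD, n = 4 each; edgeR adjusted p = 0.0353). C1qb rose 1.63-fold, and C1qc had a log2 fold change of 0.67 ± 0.11 that did not pass (edgeR adjusted p = 0.0761). Of 16 macrophage genes, 2 rose over all genes and 8 adjusted over the list alone (median log2 fold change 0.46, camera adjusted p = 5.84e-07, adjusted p = 0.0572 with an estimated correlation). Of 20 complement genes, 2 rose over all genes by edgeR, against 4 by DESeq2 and 4 by limma voom. Adjusted over the list alone, 7 rose and 1 fell (median 0.47, camera adjusted p = 1.33e-06, adjusted p = 0.0308 with an estimated correlation). C4b (22.7% of windows shared with another gene) rose 2.06-fold and by edgeR passed only when adjusted over the list alone, while DESeq2 and limma voom called it over all genes. The member lower was C7, a terminal complement component named after its value was seen (log2 fold change -0.51 ± 0.17). In the dendritic cell list, 1 of 14 members, Xcr1, rose over all genes and 2, Xcr1 and Itgax, adjusted over the list alone. Xcr1, a chemokine receptor of the dendritic cells that cross-present antigen, rose 2.44-fold (edgeR adjusted p = 0.0367), and the list had a median log2 fold change of 0.30 (camera adjusted p = 0.00754, adjusted p = 0.596 with an estimated correlation). Without DT-labelled replicate 1 the dendritic cell list was not called (camera adjusted p = 0.0638). Of 9 eosinophil genes, 0 passed over all genes by edgeR, against 3 higher at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma voom. Adjusted over the list alone 2 rose (median 0.90, camera adjusted p = 0.00193, adjusted p = 0.0778 with an estimated correlation). Siglecf, a surface marker of eosinophils, had a log2 fold change of 2.02 ± 0.37 (edgeR adjusted p = 0.107), and Alox15 one of 1.71 ± 0.50. Of 12 neutrophil genes, 0 passed over all genes by edgeR, against 6 higher and 1 lower at an unadjusted p under 0.05, 3 higher by DESeq2 and 2 by limma voom. Adjusted over the list alone, 4 rose and 1 fell (median 0.59, camera adjusted p = 0.00135, adjusted p = 0.201 with an estimated correlation). The neutrophil granule gene Ngp had a log2 fold change of 2.41 ± 0.44 (edgeR adjusted p = 0.0881) and S100a9 one of 1.72 ± 0.41. The member lower over the list alone was Ly6g, named after its value was seen, at 0.0935 ± 0.0119 CPM against 2.2 ± 2.54 CPM.

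**Figure D2:**
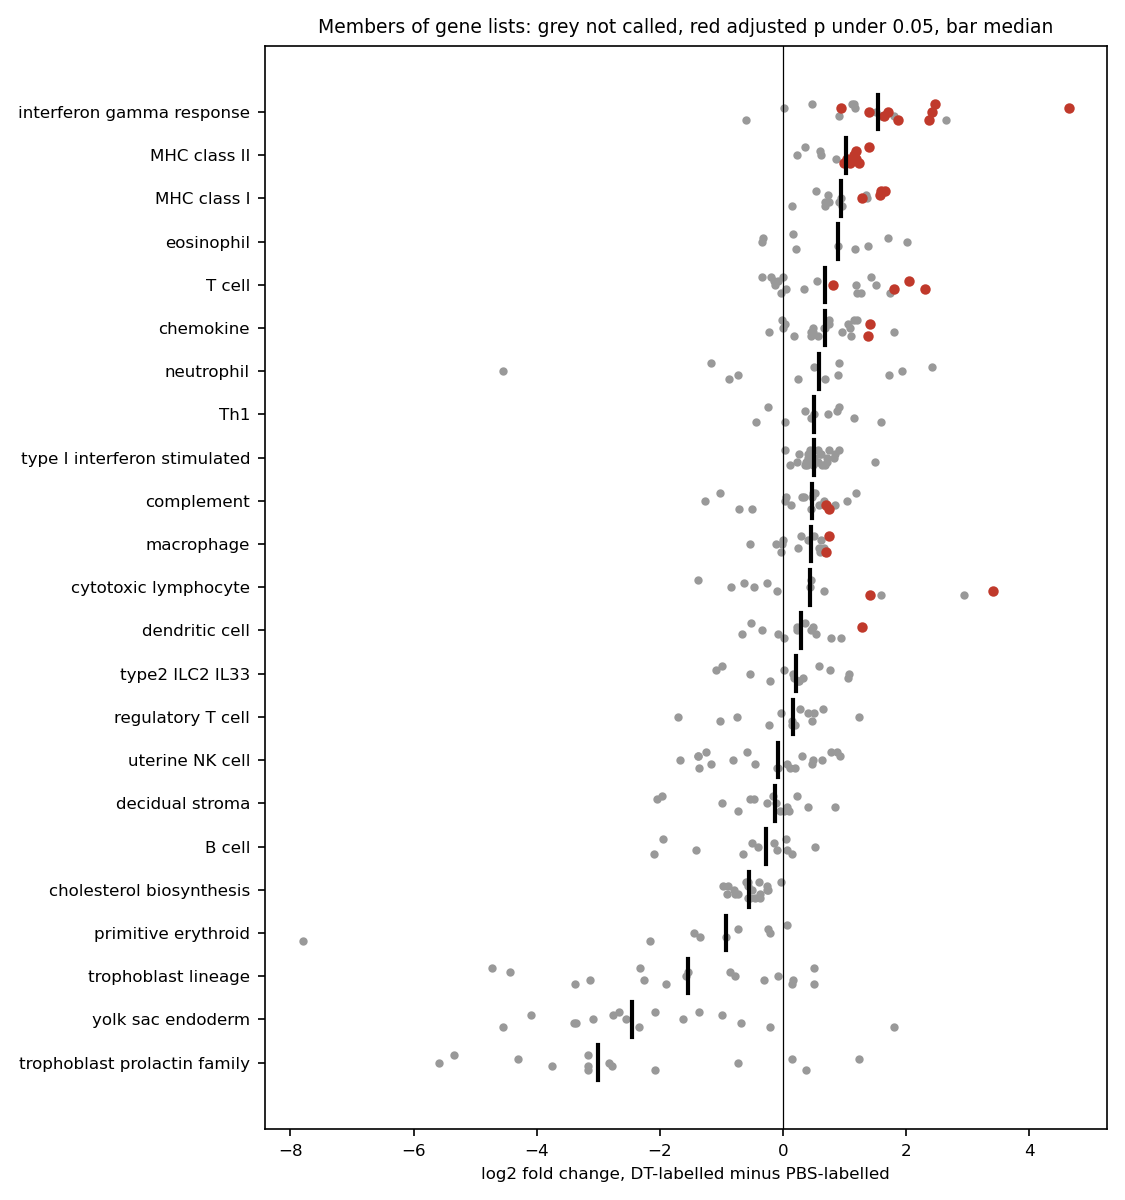
Log2 fold change (DT-labelled minus PBS-labelled) of each measured member of the 19 lists called by camera and of 4 lists that were not called, with points for genes, short bars for list medians and red for genes past an edgeR adjusted p of 0.05. The medians ran from 1.55 in the interferon-gamma list to -3 in the trophoblast prolactin list, whose members had no red points.

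Cholesterol biosynthesis, B cell and conceptus lists lay lower in the DT-labelled libraries by camera, and none of these calls held with an estimated correlation. All 20 cholesterol biosynthesis genes had negative log2 fold changes with a median of -0.55, which was -0.145 without PBS-labelled replicates 1 and 2 and -0.248 with a conceptus score as a covariate. Of the 20, 0 passed over all genes by edgeR and 0 adjusted over the list alone. At an unadjusted p under 0.05, 14 were lower, and DESeq2 and limma voom called 0 (camera adjusted p = 3.45e-11, adjusted p = 0.418 with an estimated correlation). Cyp51, which encodes lanosterol demethylase, measured 44.1 ± 2.6 CPM against 65.4 ± 17.5 CPM (SD, n = 4 each), and Hmgcs1, the synthase at the entry of the pathway, 88.2 ± 3.95 against 121 ± 27 CPM. Over the whole B cell list, 0 of 12 members passed over all genes by edgeR, against 4 lower at an unadjusted p under 0.05, 2 by DESeq2 and 1 by limma voom. The list had 3 members lower when adjusted over the list alone and a median log2 fold change of -0.28 (camera adjusted p = 0.00193, adjusted p = 0.418 with an estimated correlation). Pax5, a transcription factor of B cells, measured 0.205 ± 0.0581 CPM against 0.793 ± 0.419 CPM, a log2 fold change of -1.95 ± 0.39 (edgeR adjusted p = 0.147) that passed over all genes by DESeq2 and limma voom only.

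Genes of the conceptus differed widely between females of the same group. Yolk sac endoderm genes had a median log2 fold change of -2.45, with 0 of 16 past the test over all genes by edgeR and 9 lower adjusted over the list alone. At an unadjusted p under 0.05, 12 were lower, with 3 called by DESeq2 and 0 by limma voom (camera adjusted p = 5.84e-07, adjusted p = 0.502 with an estimated correlation). Afp, alpha-fetoprotein, measured 0.502 ± 0.184 CPM in the DT-labelled and 11.8 ± 17.9 CPM in the PBS-labelled libraries (SD, n = 4 each), a PBS-side SD larger than the mean. For trophoblast prolactins (14 members) and the trophoblast lineage (17 members), 0 members passed over all genes by edgeR and 0 adjusted over the list alone. At an unadjusted p under 0.05, 7 and 4 members were lower and 1 prolactin, Prl8a9, was higher, and DESeq2 called 2 and 1 lower and limma voom 0, with medians of -3 and -1.55 (camera adjusted p = 0.00754 and 0.0274, adjusted p = 0.688 and 0.757 with an estimated correlation). Prl7d1 had a log2 fold change of -5.59 ± 1.76 and Tpbpa, a marker of the spongiotrophoblast lineage, one of -3.38 ± 0.99 (edgeR adjusted p = 0.489 and 0.451). Primitive erythroid genes had a median of -0.92, with 0 of 9 past the test over all genes by edgeR and 0 adjusted over the list alone, 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom (camera adjusted p = 0.0295, adjusted p = 0.753 with an estimated correlation). Without PBS-labelled replicates 1 and 2, the medians turned positive for trophoblast prolactins (0.51), the trophoblast lineage (0.52) and primitive erythroid genes (0.75), while that of yolk sac endoderm genes stayed negative at -0.14. Leaving out 1 library ended camera's call of trophoblast prolactins without DT-labelled replicate 1 (adjusted p = 0.0927) or PBS-labelled replicate 2 (0.0779). The trophoblast lineage was not called without DT-labelled replicate 1 (0.304) or PBS-labelled replicate 1 (0.106) or 2 (0.407), nor were primitive erythroid genes without these 3 libraries (0.0556, 0.0517 and 0.467).

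Uterine NK cell, decidual and type 2 immunity lists showed no difference that passed the list test with all 8 libraries. Of 21 uterine NK cell genes, 0 passed over all genes by edgeR, against 5 higher and 3 lower at an unadjusted p under 0.05, 1 higher by DESeq2 and 0 by limma voom. The receptor gene Klra4 rose adjusted over the list alone, and the list had a median log2 fold change of -0.08 while camera's direction was up (adjusted p = 0.926). Klra4 had a log2 fold change of 0.87 ± 0.18 and the activating receptor gene Klrk1 one of 0.49 ± 0.16 (edgeR adjusted p = 0.153 and 0.504). Camera called the uterine NK cell list higher without PBS-labelled replicates 1 and 2 (adjusted p = 0.00283, 0.397 with an estimated correlation) and without these and DT-labelled replicate 1 (0.000678, 0.409 with an estimated correlation). Decidual stroma genes had 0 of 16 members past either adjustment by edgeR, 2 lower at an unadjusted p under 0.05, 0 by DESeq2 or limma voom, and a median of -0.13 (camera adjusted p = 0.12). The serine proteases Htra3 and Htra1 measured 184 ± 86.2 against 720 ± 575 CPM for Htra3 and 176 ± 106 against 727 ± 633 CPM for Htra1 (SD, n = 4 each). Camera called the decidual list lower without DT-labelled replicate 3 (adjusted p = 0.0389), 4 (0.0492) or 5 (0.0284). In the type 2 immunity list, 0 of 14 members passed over all genes by edgeR, against 3 higher and 2 lower at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 1 higher by limma voom. The alarmin gene Il33 rose adjusted over the list alone (median 0.21, camera adjusted p = 0.29, and called higher at 0.0453 without PBS-labelled replicates 1 and 2, 0.264 with an estimated correlation). Il33 had a log2 fold change of 0.59 ± 0.13 (edgeR adjusted p = 0.181). Camera called none of the other 32 lists. Over all 22693 genes, 1072 were higher and 903 lower at an unadjusted p under 0.05, where 1135 were expected by chance in both directions together.

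The largest variation between the 8 libraries did not follow the treatment. The first principal component of the 500 most variable genes held 74.1% of their variance and ran from -50.4 in DT-labelled replicate 1 and -26.2 in PBS-labelled replicate 4 to 36.7 and 50.8 in PBS-labelled replicates 1 and 2. Embryonic globin reads, which primitive red cells of the conceptus make, numbered 3759 and 29866 in PBS-labelled replicates 1 and 2 and between 0 and 51 in the other 6 libraries. Reads of the 4 Y-linked genes, which only male conceptuses can supply in a uterus, numbered 432 and 1718 in the same replicates and 1 to 149 in the others. Neither share differed between groups by more than the replicate spread (two-sided exact permutation p = 0.2 for embryonic globins and 0.371 for Y-linked genes). The conceptus score averaged -0.304 ± 0.353 in the DT-labelled and 0.304 ± 0.983 in the PBS-labelled libraries (SD, n = 4 each; exact permutation p = 0.314). The suffix in the sample titles, whose meaning is not given in the sources used here, paired PBS-labelled replicates 1 and 2, PBS-labelled replicates 4 and 6, DT-labelled replicates 1 and 3, and DT-labelled replicates 4 and 5. No suffix spanned both groups, so an effect of whatever it marks cannot be told apart from that of treatment. With the suffix as a term nested in treatment, 26 of the 73 genes stayed called. Shares of mitochondrially encoded genes averaged 2.31% ± 0.0308 and 2.31% ± 0.166 (exact permutation p = 1), and shares of the 10 most abundant genes 10.7% ± 2.34 and 11.9% ± 3.34 (exact permutation p = 0.571). Adult haemoglobin also did not differ (exact permutation p = 0.429). Genes that take up ribosomal RNA reads held 0.843% of the counts in PBS-labelled replicate 6 and 4.24% to 8.78% in the other libraries. With the conceptus score as a covariate, a fit chosen after the data were seen, 75 genes rose and 4 fell, 55 of the 73 among them. The interferon-gamma, MHC class II, T cell, Th1 and complement lists were then called higher with an estimated correlation (adjusted p = 0.0182 for each), as were MHC class I and chemokine (0.0233 each), macrophage (0.0318) and eosinophil genes (0.0479), and cholesterol biosynthesis (0.0479) and yolk sac endoderm genes (0.0286) were called lower. The yolk sac endoderm genes are themselves part of the score, so their call in this fit is not an independent result. Without PBS-labelled replicates 1 and 2 the smallest adjusted p of any list with an estimated correlation was 0.11, and without these and DT-labelled replicate 1 it was 0.143, so the T cell, Th1, complement and chemokine lists lost that call. In these fits, also chosen after the data were seen, the medians were 0.685 and 0.641 for T cell, 0.434 and 0.449 for Th1, 0.265 and 0.231 for complement and 0.645 and 0.502 for chemokine genes.

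**Figure D3:**
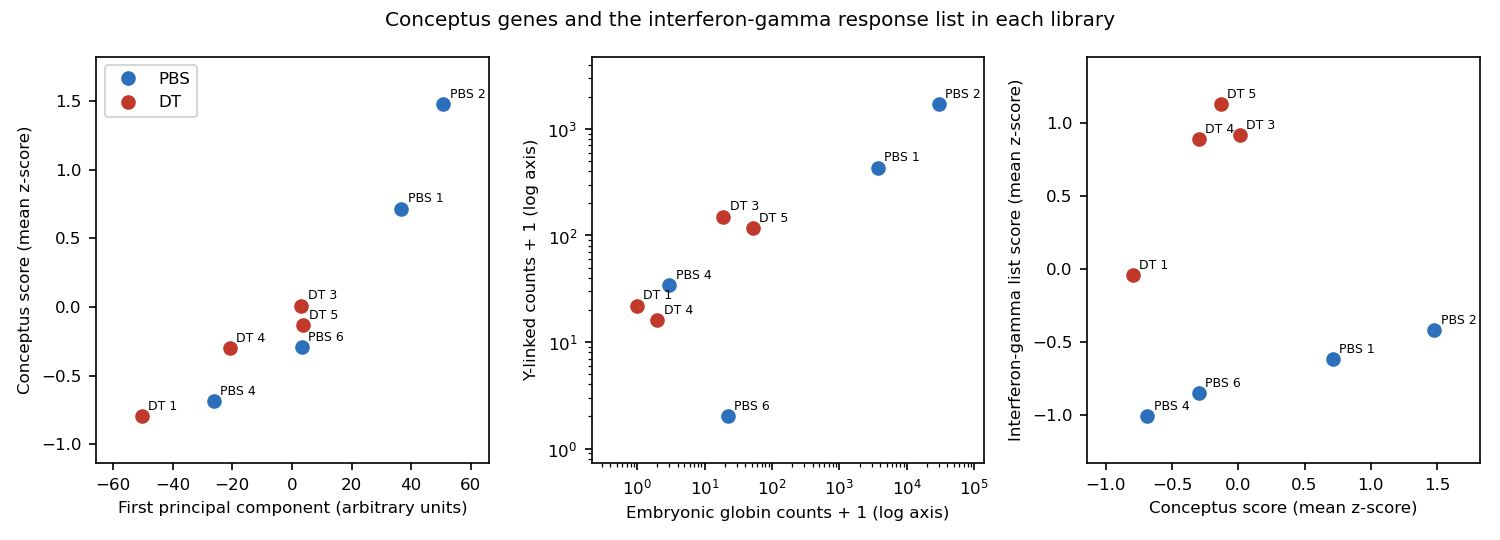
Conceptus-derived variation in the 4 DT-labelled and 4 PBS-labelled libraries, 1 point per library: the first principal component against the conceptus score, embryonic globin counts plus 1 against Y-linked counts plus 1 on log axes, and the interferon-gamma list score against the conceptus score. PBS-labelled replicates 1 and 2 stand at conceptus scores of 0.716 and 1.48, and every DT-labelled library lies above every PBS-labelled library in interferon-gamma score.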

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

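Of the tests in this part, those of conceptus stage, lymphoid tissue, shared reads, the cells behind the Foxp3 reads and developmental stage were chosen only after the result was seen. Those of other splits of the libraries, Ccdc22 and sequencing depth were chosen before, and that of ribosomal RNA was set before its result but on 3 genes picked after the data were seen.

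In 11 of 226 groups of 4 libraries, 1 library stood far from the other 3 by Dixon's test, and chance gives about 1 in 20, or 11.3. DT-labelled replicate 1 was low for 4 interferon-inducible GTPases: Tgtp1 at 6.81 CPM against 13.7 to 15.2 in the other 3, Irgm2 at 52.5 against 104 to 116, Gbp6 at 4.44 against 11.1 to 13.3, and Gbp4 at 42.9 against 85.7 to 91.8. In the same library C1qc was high at 60.9 CPM against 45.7 to 47.5. Ccl5 was low in DT-labelled replicate 4 (2.42 CPM against 2.79 to 2.87), and Ms4a1 was low in DT-labelled replicate 3 (0.03 CPM against 0.107 to 0.133). H2-DMa was low in PBS-labelled replicate 1 (4.57 CPM against 5.01 to 5.04), Rrp12 was high in PBS-labelled replicate 2 (35.5 CPM against 32.2 to 32.4), and Klrd1 was low in PBS-labelled replicate 4 (3.77 CPM against 4.69 to 4.9). Embryonic globins held 0.0279% of the counts in PBS-labelled replicate 2, against 1.97e-06% to 0.00364% in the other PBS-labelled libraries.

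Interferon, MHC and T cell genes were higher in the DT-labelled libraries. With the conceptus score as a covariate the median log2 fold change of the 73 genes was 1.2 ± 0.849 (SD over genes), against 1.28 ± 0.802 without it, and 55 stayed called, which argues against conceptus stage as the whole cause. Lymphoid tissue taken with the uterus would raise B cell genes with T cell genes, but the B cell median was -0.28. The T cell minus B cell score was higher by 1.27 in the DT-labelled libraries, in 4 of 4 above the highest PBS-labelled library (two-sided exact permutation p = 0.0286, the smallest possible). Both list medians were known when this difference was chosen, so its p is not separate support. In the lymph node list, fixed before the data were examined, 5 members were measured. Their median log2 fold change was -0.373 (camera adjusted p = 0.547). Reads shared between gene copies are not the whole cause, since 55 of the 73 genes had under 10% of their windows shared. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real split, gave as many called genes (74, highest other 0). A rate of 1 in 35 is the smallest possible here, so this argues against chance for the count but does not exclude it. At an unadjusted p under 0.05 the real split gave 1975 genes, and another split gave 7129. An immune response to the depletion of regulatory T cells, toxin effects on other cells and an effect of whatever the title suffixes mark cannot be told apart. No suffix spans both groups.

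Foxp3 was not lower in the DT-labelled libraries. In 4 of 4 PBS-labelled libraries Foxp3 lay above Cd3e, Cd3g, Cd4 and Trac, also per kilobase of exon (0.953 to 1.19 CPM for Foxp3 against 0.501 to 1.09 for Trac, the highest of the 4), so a candidate explanation is that most Foxp3 reads come from cells other than T cells, which also allows Foxp3 to lie below Trac per kilobase in the 4 DT-labelled libraries (1.11 to 1.25 against 1.71 to 2.34), where Trac was higher. Against this, Foxp3 and Cd3e log2 CPM rose together over the 8 libraries (Pearson r = 0.778, exact permutation p = 0.0257, adjusted 0.0771, Spearman rho = 0.881, exact permutation p = 0.00724, adjusted 0.0163), although r was 0.548 without the 2 libraries farthest from the median Cd3e level (PBS-labelled replicates 1 and 2). Within groups this r was 0.83 in the DT-labelled and 0.916 in the PBS-labelled libraries (n = 4 each). Reads of the overlapping gene Ccdc22 cannot be told apart from Foxp3 reads, as the correlation of both genes (r = 0.544, rho = 0.571, exact permutation p = 0.159 and 0.151, adjusted 0.286 and 0.226, r = 0.208 without the 2 farthest libraries) was neither high nor absent and the strand setting is unknown. Return of regulatory T cells after the last injection, and labels that do not match the treatment, stay open and were not tested.

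The libraries spread along the first principal component in an order that did not follow the treatment. For sequencing depth r was 0.106 (95% interval -0.647 to 0.754, rho = 0.19, exact permutation p = 0.808 and 0.665, adjusted 0.815 and 0.748), and 0.574 without the 2 libraries farthest from the median depth. Within groups this r was -0.332 in the DT-labelled and 0.833 in the PBS-labelled libraries. No relation with depth was shown, but an interval this wide cannot exclude one. The share of ribosomal RNA-like genes cannot be told apart from this order with 8 libraries (r = 0.344, 95% interval -0.476 to 0.844, rho = 0.5, exact permutation p = 0.409 and 0.216, adjusted 0.526 and 0.278, r = 0.536 without the 2 farthest). A component computed without the genes of the conceptus lists followed the conceptus score (r = 0.928, rho = 0.905, exact permutation p = 0.000397 and 0.00456, adjusted 0.00357 and 0.0137, r = 0.886 without PBS-labelled replicates 1 and 2), consistent with litters that differed in developmental stage or in the amount of conceptus tissue. PBS-labelled replicates 1 and 2 also share a title suffix, so an effect of whatever it marks stays open.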

How the results depend on the processing

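The fits with a conceptus score, without 2 or 3 libraries and without ribosomal RNA-like genes were chosen only after the results were seen, and the other alternatives were planned. Against 73 genes higher and 1 lower, DESeq2 called 270 higher and 71 lower (73 and 1 shared) and limma voom 204 and 17 (72 and 1 shared). A surrogate variable gave 218 and 8, the conceptus score 75 and 4, and the title suffix as a nested term 32 and 4, with 26 of the higher genes shared. Upper-quartile scaling and library size only each gave 2 lower, and a test against a 1.2-fold change called 21 higher. Without the 2 PBS-labelled libraries with embryonic globin, edgeR called 0 higher and 1 lower, with 687 and 170 at an unadjusted p under 0.05, 165 and 8 by DESeq2 (72 of the 73 shared), and 0 and 1 by limma voom (0 shared). Without the 3 libraries farthest out on the first component, edgeR called 61 higher and 1 lower, DESeq2 344 and 94, and limma voom 59 and 2. With 1 library left out the counts ranged from 0 to 115 higher and 0 to 5 lower. As 115 were called with 7 libraries and 61 with 5, fewer degrees of freedom alone do not account for the lost calls. The replicate number was shared by 2 pairs only, whose deviations correlated at -0.491 and 0.321. The chi-square per degree of freedom was 760 between both replicates 1 and 29.33 between both replicates 4, against a smallest of 28.81 over the 28 pairs. These values point both ways and cannot decide whether the numbers pair libraries, so the absence of pairing was assumed. With the number as a replicate block edgeR called 0 higher and 0 lower, as only 4 libraries then inform the treatment effect, with 205 and 75 at an unadjusted p under 0.05. All 73 genes stayed positive, which their lack of overlap between groups gave in advance. Of the 55 lists, 13 were higher and 6 lower. The higher lists numbered 23 with 1 surrogate variable, 25 without the 3 libraries farthest out on the first component, 27 without the 2 PBS-labelled libraries and 4 with an estimated correlation. The lower lists numbered 10 with library size only, 2 with a minimum of 1 CPM in 4 libraries, 12 with the replicate block, 0 with an estimated correlation, 0 with fry, and 3 to 10 with 1 library left out. Trophoblast prolactins, trophoblast lineage and primitive erythroid medians turned positive with 1 surrogate variable (0.189, 0.336 and 0.261), without the 3 outermost libraries (0.774, 0.953 and 0.868) and without the 2 PBS-labelled libraries (0.511, 0.515 and 0.745). With the conceptus score the trophoblast lineage median was 0.22 and the primitive erythroid median -0.0376 with camera's direction up. The reversals without libraries came with leaving out PBS-labelled replicates 1 and 2, which hold most conceptus reads, and for the other moves the cause was not tested. Foxp3 stayed uncalled in all 24 alternatives (log2 fold change 0.0673 to 0.25, adjusted p 0.282 to 1). Over all named genes and alternatives, 2069 values kept their side of the threshold, 99 gained a call and 301 lost one, and 0 called genes reversed. The sign changed for 29 estimates that were called in neither fit. For lists, 502 kept their side of the threshold, 10 gained and 49 lost a call and 11 reversed. The direction changed in 13 cases where the list was called in neither fit. The 5 composition shares moved by less than the replicate spread. In counts simulated at the depth and spread of these libraries, 4-fold changes were recovered at 94% and 1.5-fold changes at 10.4%, and neither depth nor spread was varied. Genes were simulated independently there, so these rates may not hold where genes vary together.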

Other observations

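The score differences, the correlation within groups, the genes singled out in this part and the split counts of lists were chosen only after the results were seen, except the comparison of CD8 with CD4 genes, which was planned.

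Of the 74 called genes, 30 belonged to the fixed lists, and those outside them held further immune genes, named here after their values were seen. Themis, a signalling protein of developing and mature T cells, rose 7.88-fold, from 0.0894 ± 0.037 to 0.715 ± 0.147 CPM (SD, n = 4 each; edgeR adjusted p = 0.0153). Tnfsf10, which encodes the death ligand TRAIL, rose 2.06-fold, from 14.4 ± 1.87 to 29.8 ± 1.39 CPM (edgeR adjusted p = 0.0153). Vcam1, an endothelial and stromal adhesion molecule for leukocytes, rose 1.82-fold, from 6.62 ± 0.864 to 12.1 ± 0.526 CPM (edgeR adjusted p = 0.0322). The inhibitory receptor gene Lair1 rose 2.04-fold, and the macrophage genes Mpeg1 and Aif1 rose 1.59- and 1.94-fold. Predicted gene models made up 14 of the 74.

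Members of the uterine NK cell list went both ways. Klra4, Klrk1, Klrd1, Klra8 and Klra9 (12.1% of windows shared with another gene), which encode NK receptors, had positive log2 fold changes from 0.31 to 0.87, all at an unadjusted p under 0.05. Gzma, Gzmc and Prf1, which encode granzymes and perforin, had log2 fold changes of -0.81, -1.38 and -1.38, also at an unadjusted p under 0.05, and none passed over all genes by edgeR (DESeq2 called 1 of the 21 members and limma voom 0). Other receptor genes of the list lay on both sides of 0, from -0.58 for Il2rb to 0.92 for Klrc1, and a division by kind of gene was not tested. Between females Prf1 varied widely, at 45.6 ± 14.6 CPM in the DT-labelled and 119 ± 80.4 CPM in the PBS-labelled libraries (SD, n = 4 each). The list score followed the conceptus score over the 8 libraries in rank (rho = 0.905, exact permutation p = 0.00456, adjusted 0.0137), while Pearson's r was 0.691 (exact permutation p = 0.0667, adjusted 0.15) and 0.709 without the 2 farthest libraries. Smooth muscle genes went the other way, with r = -0.834 (exact permutation p = 0.00856, adjusted 0.0385), rho = -0.905 (exact permutation p = 0.00456, adjusted 0.0137) and r = -0.911 without the 2 farthest libraries. For decidual stroma genes r was 0.409 (exact permutation p = 0.271, adjusted 0.406) and rho 0.571 (exact permutation p = 0.151, adjusted 0.226), and r was 0.803 without the same 2 libraries, PBS-labelled replicates 1 and 2.

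Whether the immune changes have a preferred kind was tested with 4 differences of mean log2 CPM, of which 3 are given here, and each was higher in all 4 DT-labelled libraries than in the highest PBS-labelled library (two-sided exact permutation p = 0.0286 each, adjusted 0.0286, the smallest possible). The interferon-gamma minus type I interferon score, without shared members, was -0.462 ± 0.149 in the DT-labelled and -1.47 ± 0.111 in the PBS-labelled libraries (SD, n = 4 each), a difference of 1.01, so the lists did not rise alike. The medians of both lists were known when this difference was chosen, and it cannot tell which interferon acted. MHC class II minus macrophage and dendritic cell genes differed by 0.615, from -0.31 ± 0.155 to 0.305 ± 0.0882, so class II genes rose more than these 2 lists did. The medians of these lists were also known when this difference was chosen. It therefore cannot decide whether more macrophages and dendritic cells alone caused the class II change. Cd8a and Cd8b1 minus Cd4 differed by 1.96, from -2.32 ± 0.859 to -0.356 ± 0.591, which argues against CD4 and CD8 genes rising alike in fold. Their levels in the PBS-labelled libraries were unequal. Mean CPM went from 0.667 to 1.51 for Cd4, from 0.206 to 1.6 for Cd8a and from 0.0879 to 0.963 for Cd8b1. The comparison therefore holds for folds and not for amounts in CPM.

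Interferon-gamma list scores rose with the conceptus score within the PBS-labelled group, while the relation in the DT-labelled group rested on replicate 1. With both scores centred within groups, r was 0.697 (two-sided exact permutation within groups, p = 0.00521, 576 arrangements, n = 8), and r was 0.924 in the DT-labelled and 0.995 in the PBS-labelled libraries (n = 4 each). Without DT-labelled replicate 1, r was 0.155 in the other 3 DT-labelled libraries, and 0.92 over both groups (exact permutation p = 0.0347, n = 7). Among PBS-labelled replicates 4, 6, 1 and 2 the conceptus scores were -0.686, -0.295, 0.716 and 1.48 and the interferon-gamma scores -1.01, -0.849, -0.618 and -0.419. Replicates 1 and 2, with the higher values of both scores, share a title suffix, as do replicates 4 and 6. An effect of whatever the suffix marks therefore stays open for this relation. Among DT-labelled replicates 1, 4, 5 and 3 the conceptus scores were -0.798, -0.299, -0.13 and 0.0105 and the interferon-gamma scores -0.0429, 0.89, 1.13 and 0.917. Pooled over the 8 libraries, where the groups lie apart, r was -0.107 (exact permutation p = 0.815, adjusted 0.815), rho 0.143 (exact permutation p = 0.752, adjusted 0.752), and r 0.64 without the 2 farthest libraries.

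List calls with the preset correlation were common in other splits of the libraries. The real split gave 19 lists, and the other 34 splits gave 5 to 29, with 14 giving as many or more. With an estimated correlation the real split gave 4 lists and each of the others 0. At an unadjusted p under 0.05 the real split gave 1975 genes and the others 103 to 7129, with the most when DT-labelled replicates 1, 3 and 4 and PBS-labelled replicate 4 were set against the rest. That split follows the order of the libraries on the first principal component, where DT-labelled replicate 3 (3.12) lay next to PBS-labelled replicate 6 (3.23) and DT-labelled replicate 5 (3.54), and the split by conceptus score gave 6606 genes. Both point to a structure of the samples other than treatment.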
